A study of Caenorhabditis elegans with 9 samples.

How the data were processed

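The study compared first-stage (L1) larvae of Caenorhabditis elegans with 3 genotypes on Affymetrix arrays: wild type, a strain labelled as carrying the ok430 deletion of ogt-1, and a strain labelled as carrying the ok1207 deletion of oga-1. OGT-1 is the enzyme that attaches the sugar O-GlcNAc to nuclear and cytoplasmic proteins, and OGA-1 is the enzyme that takes it off. Per the labels' protocols, eggs freed by bleaching hatched without food, the larvae were collected after 48 h, given OP50 bacteria for 3 h and taken for RNA. Total RNA was extracted with Trizol, and 4 ug was made into biotin-labelled cRNA per the labels' protocols. Each genotype had 3 arrays, labelled as biological replicates 1 to 3, which makes 9 arrays.

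The deposited values are 1 log2 signal per probe set and array, in a single table of the whole series. The submitters' processing notes name MAS5, RMA and Partek, without versions and without saying what each was used for. How the array scans were summarised and scaled, and the base of the logarithm, are not given in the sources used here. The values were taken as log2 because they run from 3.74 to 14.9 and the array medians from 7.42 to 7.47. The near-equal medians show that the arrays had been brought to 1 scale before they were deposited, so a change common to most genes could not be seen. No raw intensities were used, so background and detection calls were not assessed, and low signals have no stated floor.

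The table holds 22625 probe sets. The 77 control probe sets were left out of the tests and used as quality measures, and the other 22548 were tested without a filter on low signal. In the platform annotation 20766 tested probe sets carried 1 gene symbol, which covers 17118 genes. Another 887 carried several symbols and 895 carried none, and no gene was named from those. Of the probe sets with 1 symbol, 20701 matched the RefSeq gene table of the WBcel235 assembly, which was used for current names and for the order of genes only. The identifiers of 6711 probe sets mark possible cross-hybridisation with related sequences, and genes measured by such a probe set are called uncertain. Of the genes, 2981 had more than 1 probe set, and the one with the highest mean over all arrays stood for the gene in the lists.

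Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with all 9 arrays in 1 model, a coefficient per genotype and no block. The model left 6 residual degrees of freedom, to which the moderation added 3.92. P-values were adjusted by Benjamini-Hochberg over the 22548 probe sets, and a probe set was called at an adjusted p under 0.05. Changes are differences of group means on the log2 scale with the model's standard error (SE), and folds are 2 to the power of the size of that difference. Comparisons of a single quality value used a two-sided exact permutation test of 3 arrays against 3, whose smallest possible p is 0.1.

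Before the data were examined, 47 gene lists were fixed (pathways, gene families, tissue markers, and markers of embryos or adults that a larval sample could hold), together with the tests and the rule for naming genes. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 47 lists within a comparison. Camera with a correlation estimated per list and limma's fry were run beside it, with fry's directional and mixed tests. The counts of list members use the adjustment over all genes, and a second count is adjusted over the list alone. The naming rule took the 10 genes with the largest rise and the 10 with the largest fall in each comparison with wild type (the 6 each way between the mutants) among called probe sets with 1 symbol, whose higher group mean was at or above the median of all probe set means (7.45) and whose groups did not overlap. It further took ogt-1 and oga-1, up to 4 members of each described list by smallest p (2 where none was called), and the 6 genes with the largest change shared by both mutants in the same direction and in opposite directions.

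Both mutants were set against the same 3 wild-type arrays, so their changes share the chance values of those arrays. To measure this, 100 simulated data sets with unchanged mutant groups were compared with the same wild-type arrays. After the data were seen, simulated mutants with unrelated changes were added, 100 data sets in each of 2 settings. Called changes kept their estimated size, those of the oga-1 mutant moved to other probe sets of like error, and the other changes were 0 or shrunk by their error. Also after the data were seen, probe sets called in both mutants without 1 wild-type array were measured against that array, which had no part in their choice. Limma and camera were run on data simulated from these arrays' means and spreads. For simulated ogt-1 mutant against wild type over 22548 probe sets, 40.3% of genes changed by 0.5 log2 were called, 95.5% of those by 1 and 100% of those by 2, with 12 false calls among 169. The second, unchanged, simulated mutant gave 0 calls. Camera called the 1 list shifted by 0.3 and no other, but data from means and spreads alone do not test its preset correlation.

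The labels give the genotypes the same replicate numbers but do not say that a number marks a shared culture or day. Arrays with the same number deviated together from their group means in the pairing check of ogt-1 mutant with wild type (r = 0.192, 0.100 and 0.303 for replicates 1, 2 and 3) and of ogt-1 mutant with oga-1 mutant (0.107, 0.200 and 0.322). Fits with the replicate number as a block are therefore printed beside the results of those 2 comparisons where they change a call or move a count by over 1.5 times. The pairs of oga-1 mutant and wild type were not all above 0.1.

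Alternatives fixed beforehand were quantile normalisation, median centring, removal of the dimmest 40% of probe sets, a trended and robust prior, no moderation, the 2 compared groups only, array weights, the replicate block, a limit of 2-fold, an adjusted p under 0.01, 1 probe set per gene, removal of probe sets marked for cross-hybridisation, and leaving out each array in turn. For the lists they were an estimated correlation, fry, ranks, and the mean of a gene's probe sets. After the data were seen, a covariate for the gap between 3-prime and 5-prime signal of the actin, GAPDH and ubiquitin controls was added, as was a fit without 3 arrays that stood apart on control signal or principal components (ogt-1 mutant 1, wild type 1 and oga-1 mutant 3). The plots were drawn with matplotlib 3.10.9.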

Results

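Gene expression was measured in L1 larvae of C. elegans that had hatched without food and then fed for 3 h, in wild type and in strains deleted for ogt-1 or oga-1, the enzymes that add and remove the O-GlcNAc modification of intracellular proteins. Each genotype had 3 arrays, labelled as biological replicates, and the values are deposited log2 signals of 22548 probe sets. The number of arrays limits the precision of every comparison. Arrays of 1 genotype correlated with r from 0.992 to 0.997 across probe sets and arrays of different genotypes with r from 0.985 to 0.995. The first principal component held 32.2% of the variance and set the ogt-1 mutant arrays (14.1 to 33.3) apart from the other 6, all of which were negative. On the second (19.7%), wild type 1 (24.6) and oga-1 mutant 3 (-27.7) lay at the ends. The hybridisation spikes averaged 11.05, 10.67 and 10.63 on ogt-1 mutant 1 to 3, 10.53 to 10.57 in wild type and 10.40 to 10.63 in the oga-1 mutant. The 3-prime signal of the catalase control exceeded its 5-prime signal by 0.949 ± 0.206 (SD, n = 3) in wild type, 1.74 ± 0.390 in the ogt-1 mutant and 1.04 ± 0.0812 in the oga-1 mutant. For ogt-1 mutant against wild type the exact permutation p was 0.1, the smallest possible, for spikes, catalase and ubiquitin, 0.2 for GAPDH and 0.4 for actin. For oga-1 mutant against wild type it was 0.1 for actin (difference -0.169). The mean gap of actin, GAPDH and ubiquitin, later used as a covariate, was 1.30 ± 0.0434 in wild type, 1.43 ± 0.106 in the ogt-1 mutant and 1.22 ± 0.0624 in the oga-1 mutant. Its exact permutation p against wild type was 0.2 (ogt-1 mutant) and 0.3 (oga-1 mutant). The mutants' arrays did not overlap in it (difference 0.217, exact permutation p = 0.1). Background was not assessed, so a change from or to a low signal may be understated. Folds are given only where both group means lay above the median of all probe set means (7.45).

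The deleted genes themselves were examined first. The oga-1 signal was lower in the oga-1 mutant than in wild type at all 3 of its probe sets. One of those marked for cross-hybridisation (suffix _s_at) fell from 9.49 to 8.75 (log2 change -0.75 ± 0.10 SE, n = 3, limma adjusted p = 0.0181), with 9.31, 9.54 and 9.63 on the wild-type arrays and 8.63, 8.74 and 8.88 on the mutant arrays. The other oga-1 probe sets gave -0.58 ± 0.11 (unmarked, adjusted p = 0.0648) and -0.30 ± 0.11 (marked, suffix _x_at, adjusted p = 0.373). The call of the first was lost without wild type 2 or 3 or oga-1 mutant 1 or 2 (adjusted p = 0.0595 to 0.112), and the unmarked one was called, at -0.70, without oga-1 mutant 2. The ogt-1 signal was not lower in the ogt-1 mutant. Both ogt-1 probe sets are marked (_s_at). The signal rose at the dimmer one from 9.18 to 9.88 (0.70 ± 0.11, adjusted p = 0.0141) and measured 10.86 and 11.34 at the brighter one (0.48 ± 0.17, adjusted p = 0.187). The call at the dimmer one was lost without wild type 2 or 3 or ogt-1 mutant 1 (adjusted p = 0.0527 to 0.0759). Where these probes lie relative to the deletions is not given in the sources used here, so the ogt-1 signal does not check the genotype of the arrays labelled ogt-1 mutant, and directions below rest on those labels. In the ogt-1 mutant the oga-1 probe sets gave 0.10, 0.08 and 0.12, and in the oga-1 mutant the ogt-1 probe sets gave -0.29 and -0.08, none of them called.

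**Figure D1:**
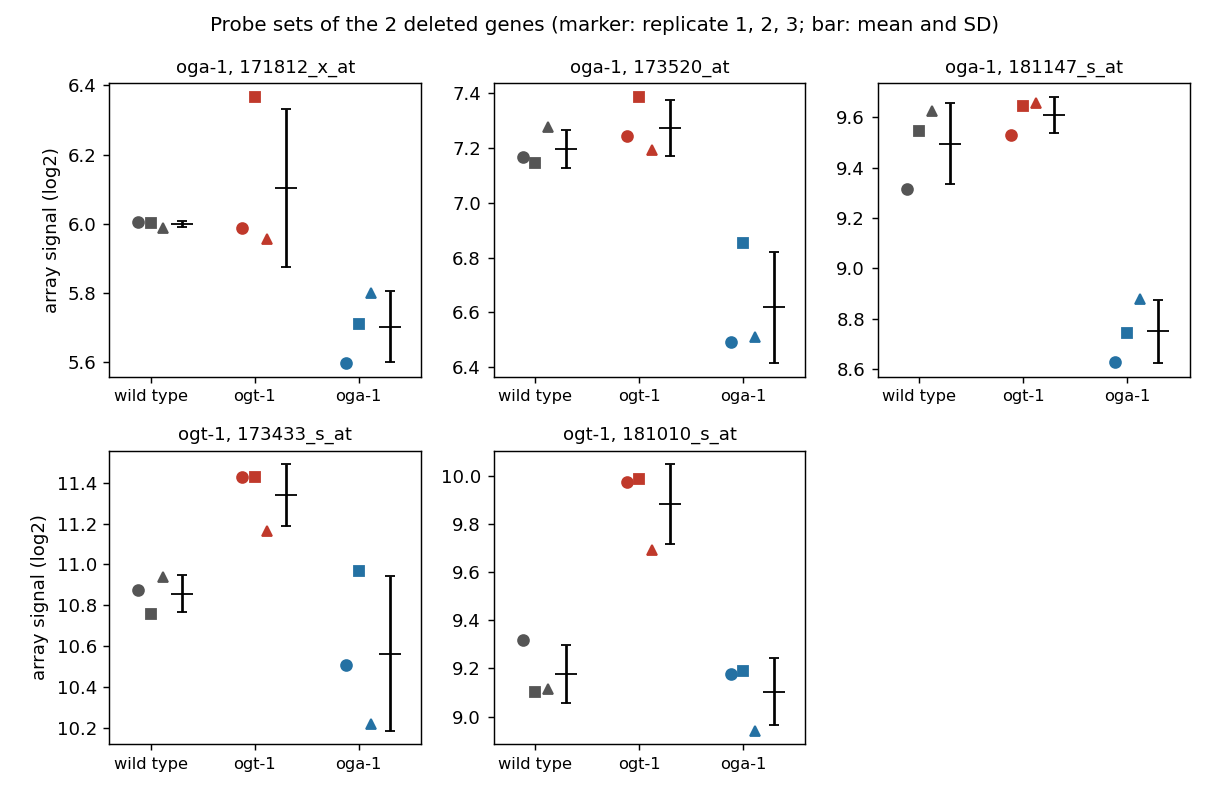
Log2 array signal of the 3 oga-1 and 2 ogt-1 probe sets in each genotype, with a circle, square and triangle for replicates 1, 2 and 3 and a bar for the mean and SD (n = 3). At the oga-1 probe set with suffix _s_at the oga-1 mutant arrays lie between 8.63 and 8.88, below the wild-type arrays at 9.31 to 9.63, and at the dimmer ogt-1 probe set the ogt-1 mutant arrays lie above the wild-type arrays.

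What loss of the O-GlcNAc transferase changes in fed L1 larvae was examined by comparing the ogt-1 mutant with wild type. The largest rise was that of cpr-4, a cathepsin B-like cysteine protease, which went from 8.27 to 12.83 (23.5-fold, log2 change 4.55 ± 0.18 SE, n = 3, limma adjusted p = 4.51e-06). The adaptor gene shc-1, which acts in insulin-like signalling, rose 7.67-fold (2.94 ± 0.19, adjusted p = 1.89e-04). That probe set is marked for cross-hybridisation, and the other probe sets of shc-1 also rose, by 2.87 ± 0.18 (marked) and 1.23 ± 0.25 (unmarked, adjusted p = 0.0367). The UDP-glucuronosyltransferase ugt-13 rose by 2.22 ± 0.19, the C-type lectin clec-3 by 1.86 ± 0.21 and the antimicrobial peptide gene cnc-4 by 2.09 ± 0.38. Among the genes that fell were prg-1, which encodes a Piwi-class Argonaute protein (-1.64 ± 0.12, adjusted p = 3.61e-04, probe set marked), the lipase-related gene lips-15 (-1.95 ± 0.18, adjusted p = 7.79e-04), and pud-4 and pud-3, a pair of related genes (-2.28 ± 0.32 and -2.1 ± 0.41). The wild-type means of ugt-13 (6.45) and clec-3 and the mutant means of pud-4 (5.88) and pud-3 lay below that median.

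In total 584 probe sets were called in the ogt-1 mutant, 268 higher and 316 lower, with a median size of change of 0.67. They covered 515 genes, and 39 had no single gene name. The limit of 2-fold was passed by 105 of them (61 higher, 44 lower). Under the naming rule the other rises were those of catp-2, a cation-transporting ATPase (2.23 ± 0.47), F56A4.10 (2.21 ± 0.19, marked), pugs-11 (2.13 ± 0.33), ZK6.8 (1.85 ± 0.31) and R12G8.1 (1.83 ± 0.30). The other falls were those of Y41C4A.32 (-2.01 ± 0.16), T22F3.11 (-1.97 ± 0.30, marked), K08B12.3 (-1.62 ± 0.15), F10C2.7 (-1.53 ± 0.29), tag-293 (-1.45 ± 0.26) and scl-24, of the SCP-like extracellular proteins (-1.40 ± 0.20). The wild-type means of catp-2, F56A4.10 and pugs-11 and the mutant means of Y41C4A.32, T22F3.11 and tag-293 lay below the median of 7.45. Of the 20 genes, cpr-4, shc-1, ugt-13, F56A4.10 and clec-3 and, among those that fell, pud-4, Y41C4A.32, lips-15, prg-1, K08B12.3 and scl-24 were called without each array in turn. The others lost the call without 1 array. These were catp-2 (without wild type 1 or 2, ogt-1 mutant 1, 2 or 3 or oga-1 mutant 2, adjusted p = 0.0659 to 0.149), cnc-4 (wild type 2 or ogt-1 mutant 1, 2 or 3, 0.0529 to 0.10), pugs-11 (wild type 2 or ogt-1 mutant 1, 0.0554 to 0.0588), ZK6.8 (wild type 2 or ogt-1 mutant 3, 0.0579 to 0.0715) and R12G8.1 (ogt-1 mutant 1, 0.0690). Among those that fell they were pud-3 (wild type 2 or 3, ogt-1 mutant 1 or oga-1 mutant 1 or 2, 0.0504 to 0.123), T22F3.11 (wild type 2 or ogt-1 mutant 1, 0.0539 to 0.0573), F10C2.7 (wild type 1, 2 or 3 or ogt-1 mutant 1 or 3, 0.0509 to 0.113) and tag-293 (wild type 2 or 3 or ogt-1 mutant 1, 2 or 3, 0.0586 to 0.0765). The count was 138 without wild type 2, 248 without wild type 3, 188 without ogt-1 mutant 1, 252 without ogt-1 mutant 3 and 357 without oga-1 mutant 2. With the replicate number as a block 1034 probe sets were called (435 higher, 599 lower), with the gap between 3-prime and 5-prime control signal as a covariate 49, and without the 3 arrays that stood apart 262.

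**Figure D2:**
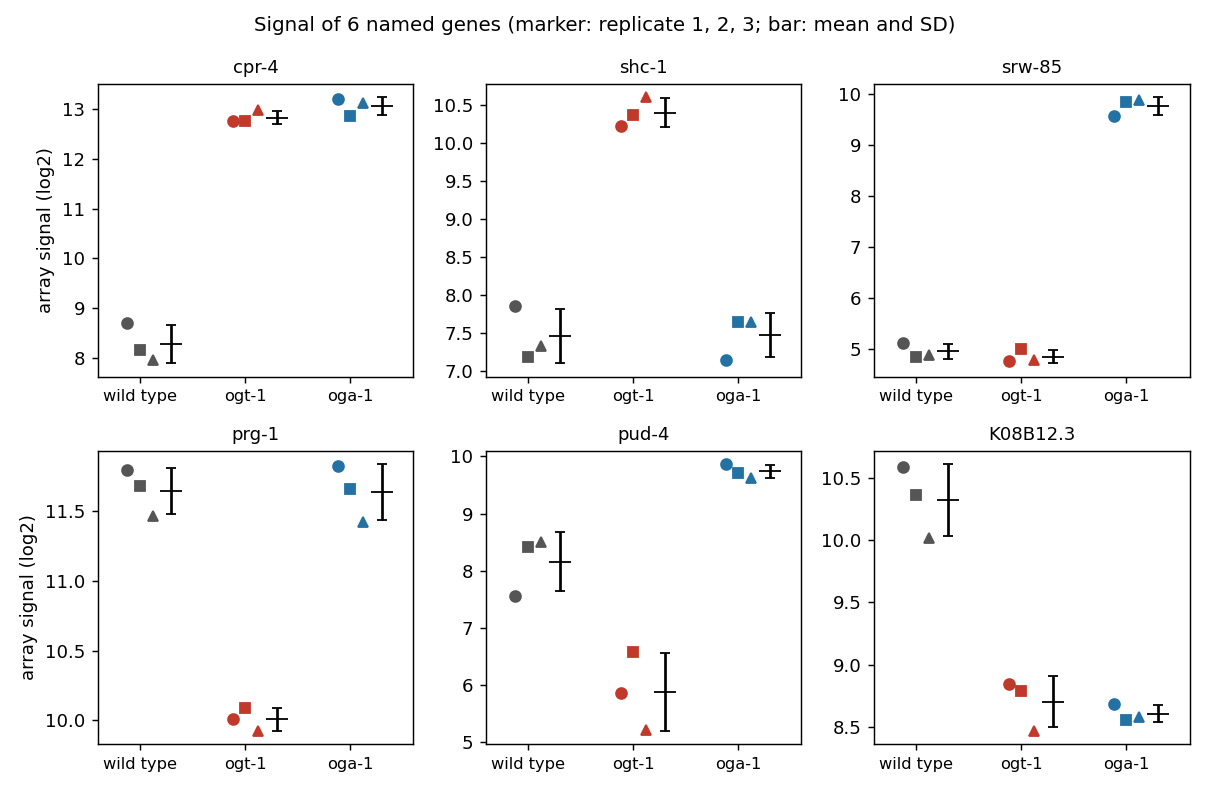
Log2 array signal of cpr-4, shc-1, srw-85, prg-1, pud-4 and K08B12.3 in wild type, the ogt-1 mutant and the oga-1 mutant, with a marker per replicate and a bar for the mean and SD (n = 3). The signal of cpr-4 has means of 8.27 in wild type, 12.83 in the ogt-1 mutant and 13.06 in the oga-1 mutant, while that of srw-85 has means of 4.96, 4.86 and 9.76.

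Of the 47 gene lists, 11 were called by camera in the ogt-1 mutant, 4 higher and 7 lower, and 0 were called with an estimated correlation (lowest adjusted p = 0.824) or by fry's directional test (lowest adjusted p = 0.154). Fry's mixed test, which takes changes either way, called 33. The list of fatty acid synthesis and desaturation was called lower at the preset correlation, with a median of -0.19 (camera adjusted p = 3.92e-04, adjusted p = 0.824 with an estimated correlation). Of 38 measured, 0 rose, 2 fell and 36 were not called, with 10 lower when adjusted over the list alone. The elongase gene elo-4 fell by 0.62 ± 0.08 and the desaturase gene fat-2 by 0.42 ± 0.09. The fall of elo-4 was called without each array in turn, and that of fat-2 was lost without any 1 of the 9 arrays (adjusted p = 0.0517 to 0.193). Of 58 genes of the citric acid cycle and respiratory chain 1 fell, sdha-2, which encodes a succinate dehydrogenase subunit (-0.72 ± 0.12, marked), and 57 were not called, with the same count over the list alone. The call of sdha-2 was lost without wild type 2 or ogt-1 mutant 1 (adjusted p = 0.0614 to 0.10). Their median was -0.14 (camera adjusted p = 3.38e-05, adjusted p = 0.824 with an estimated correlation). Among 48 germline and maternal genes 3 fell, namely prg-1, deps-1 (-0.62 ± 0.13) and csr-1 (-0.58 ± 0.12), which act in germ granules or small RNA pathways, 45 were not called, and 4 were lower over the list alone. The fall of prg-1 was called without each array, while that of csr-1 was lost without any 1 of the 9 arrays (adjusted p = 0.0573 to 0.174). That of deps-1 was lost without any wild-type or ogt-1 mutant array or oga-1 mutant 2 (0.0533 to 0.177). The median was -0.16 (camera adjusted p = 3.38e-05, adjusted p = 0.824 with an estimated correlation), and -0.11 without wild type 2, -0.09 without ogt-1 mutant 2 and -0.26 with the control gap as a covariate. Of 42 genes of cell cycle and DNA replication the ribonucleotide reductase gene rnr-1 fell (-0.55 ± 0.12, marked) and 41 were not called, with 1 lower over the list alone. The call of rnr-1 was lost without any 1 array but wild type 1 (adjusted p = 0.0515 to 0.189). The list median was -0.17 (camera adjusted p = 0.00224, adjusted p = 0.894 with an estimated correlation), and the call was lost without wild type 2 (adjusted p = 0.0557).

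Lists of detoxification and intestinal genes were also called lower in the ogt-1 mutant at camera's preset correlation but not with an estimated correlation (adjusted p = 0.824 for each), and each held a gene that rose. Of 73 cytochrome P450 genes, cyp-34A1 rose (0.61 ± 0.10), 4 fell, including cyp-34A5 (-0.72 ± 0.12) and cyp-33E2 (-0.46 ± 0.09), and 68 were not called, with 1 higher and 7 lower over the list alone. The median was -0.17 (camera adjusted p = 0.00458, adjusted p = 0.824 with an estimated correlation, and adjusted p = 0.0503 without ogt-1 mutant 3). The cytochrome P450 median was -0.10 without ogt-1 mutant 1 and -0.11 without ogt-1 mutant 3. Of 64 UDP-glucuronosyltransferases, ugt-13 rose, 4 fell, including ugt-4 (-0.62 ± 0.11), ugt-26 (-0.62 ± 0.11) and ugt-62 (-0.85 ± 0.16), and 59 were not called, with 1 higher and 10 lower over the list alone. The median was -0.12 (camera adjusted p = 0.0110, adjusted p = 0.824 with an estimated correlation, and adjusted p = 0.185 without ogt-1 mutant 3). Of 37 markers of the intestine, cpr-4 rose while the related protease gene cpr-5 (-1.13 ± 0.15, marked), the proton exchanger gene nhx-2 (-0.74 ± 0.16) and the transcription factor gene elt-7 (-0.77 ± 0.17) fell. The other 33 were not called, and 2 were higher and 9 lower over the list alone. The median was -0.20 (camera adjusted p = 0.00458, adjusted p = 0.824 with an estimated correlation, and adjusted p = 0.0735 without wild type 1, where the median was -0.11). The 4 cytochrome P450 genes that fell were 0 without wild type 2 or ogt-1 mutant 3, 1 without wild type 3, ogt-1 mutant 1 or oga-1 mutant 2, and 2 without ogt-1 mutant 2 or oga-1 mutant 1. The call of cyp-34A1 was lost without wild type 2 or 3 or ogt-1 mutant 3 (adjusted p = 0.0527 to 0.0722) and that of cyp-34A5 without wild type 2 or ogt-1 mutant 1 or 3 (0.0534 to 0.0879). That of cyp-33E2 was lost without any 1 array but ogt-1 mutant 1 (0.0525 to 0.149). The 4 UDP-glucuronosyltransferases that fell were 1 without wild type 2 or 3 and 0 without ogt-1 mutant 1 or 3. The call of ugt-4 was lost without wild type 2 or 3 or ogt-1 mutant 1 or 3 (adjusted p = 0.0525 to 0.102). That of ugt-26 was lost without wild type 1 or 3 or ogt-1 mutant 1 or 3 (0.0519 to 0.0847). That of ugt-62 was lost without wild type 2 or ogt-1 mutant 1 or 3 (0.0862 to 0.0983). Of the intestine markers cpr-4 and cpr-5 were called without each array, nhx-2 was lost without any wild-type or ogt-1 mutant array or oga-1 mutant 2 (0.0577 to 0.151) and elt-7 without wild type 2 or 3, ogt-1 mutant 1 or 3 or any oga-1 mutant array (0.0720 to 0.177). With the mean gap of actin, GAPDH and ubiquitin as a covariate, in which the ogt-1 mutant and wild-type arrays overlapped, 5 list calls were lost. The median shrank by over 1.5 times for the citric acid cycle and respiratory chain (-0.14 to -0.05, adjusted p = 0.0872), UDP-glucuronosyltransferases (-0.12 to -0.07, 0.142) and intestine (-0.20 to -0.11, 0.224), and by less for cytochrome P450 (-0.17 to -0.12, 0.0537) and histones (0.14 to 0.11, 0.0537). Without the 3 arrays the calls of intestine (0.12, median -0.13) and UDP-glucuronosyltransferases (0.0519, median -0.11) were lost.

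Lists called higher in the ogt-1 mutant at camera's preset correlation were innate immune effectors, neuropeptides, sperm genes and histones, none of them with an estimated correlation (adjusted p = 0.824 to 0.894). Of 97 innate immune effectors 7 rose, 0 fell and 90 were not called, and 10 were higher and 4 lower over the list alone. Besides cnc-4, sysm-1 (1.74 ± 0.27), dod-24 (1.49 ± 0.25, marked) and cnc-2 (1.74 ± 0.34, marked) rose. The median was 0.10 (camera adjusted p = 0.0126, adjusted p = 0.824 with an estimated correlation, and adjusted p = 0.199 without ogt-1 mutant 2), and it was 0.06 without ogt-1 mutant 2 or 3. Of 109 neuropeptides 5 rose and 104 were not called, with 8 higher and 1 lower over the list alone. They included the insulin-like peptide genes ins-3 (1.13 ± 0.14), ins-11 (1.01 ± 0.16, marked) and ins-4 (0.92 ± 0.16). The median was 0.06 (camera adjusted p = 0.0149, adjusted p = 0.894 with an estimated correlation), and the call was lost without wild type 2 (adjusted p = 0.248, median 0.01) or ogt-1 mutant 3 (0.0847, median 0.03), while the median was 0.10 without the 3 arrays. Of 77 sperm genes spe-4 rose (0.64 ± 0.12) and 76 were not called, with 1 higher over the list alone. Their median was 0.09 (camera adjusted p = 0.00458, adjusted p = 0.824 with an estimated correlation, and adjusted p = 0.0538 without the 3 arrays, where it was 0.04), and 0.06 without wild type 3 and 0.04 without ogt-1 mutant 1. None of 26 histones was called over all genes or over the list alone, and those with the smallest p were his-1 (0.36 ± 0.14, adjusted p = 0.259) and his-64 (0.38 ± 0.16, adjusted p = 0.294), both marked. With the block his-1 was called (adjusted p = 0.0489). The histone median was 0.14 (camera adjusted p = 0.0161, adjusted p = 0.894 with an estimated correlation), and the call was lost without wild type 1 (adjusted p = 0.369, median 0.05), ogt-1 mutant 2 (0.0556) or ogt-1 mutant 3 (0.244, median 0.07). The 7 innate immune effectors that rose were 1 without wild type 2 or any ogt-1 mutant array and 3 without oga-1 mutant 2 or 3. The 5 neuropeptides that rose were 1 without wild type 2, 2 without ogt-1 mutant 3, and 3 without ogt-1 mutant 1 or 2 or oga-1 mutant 2 or 3. The call of sysm-1 was lost without ogt-1 mutant 1 (adjusted p = 0.0527) and that of dod-24 without wild type 2 or 3 or ogt-1 mutant 2 or 3 (0.05002 to 0.0845). That of cnc-2 was lost without wild type 1 or 2, any ogt-1 mutant array or oga-1 mutant 2 or 3 (0.0514 to 0.133). The call of ins-11 was lost without wild type 2 (0.0588) and that of ins-4 without wild type 2 or 3 or ogt-1 mutant 3 (0.0507 to 0.102). That of spe-4 was lost without any wild-type array or ogt-1 mutant 1 or 2 (0.05004 to 0.0813). With the block 4 further lists passed, namely fatty acid breakdown and lipolysis (lower, adjusted p = 0.0239), and gluconeogenesis and glyoxylate cycle (0.0477), hypoxia and H2S response (0.0477) and neurons (0.0493), all higher. None of these passed without the block (camera adjusted p = 0.0651 for the first and 0.0517 for the others), where adjusted p = 0.824 with an estimated correlation, or 0.894 for neurons.

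Other lists held called members in the ogt-1 mutant but were not called by camera. Of 52 glutathione S-transferases and SKN-1 targets 6 rose, 1 fell and 45 were not called, with 9 higher and 4 lower over the list alone. They included gst-4 (1.44 ± 0.23), gst-14 (1.00 ± 0.15) and nit-1 (0.97 ± 0.15), while gst-22 fell (-0.59 ± 0.10). Rises were more frequent in this list than among other genes (odds ratio 10.5, Fisher's exact adjusted p = 0.00216 over 47 lists), but the camera adjusted p of the list was 0.640 (median 0.00). With the control gap as a covariate this list was called higher (adjusted p = 0.0227, median 0.08). Of 45 insulin-like signalling components shc-1, ins-3, ins-11 and ins-4 rose, 0 fell and 41 were not called, with 4 higher and 2 lower over the list alone (camera adjusted p = 0.0675, median 0.05). That list was called higher without wild type 3 (adjusted p = 0.0326) and without ogt-1 mutant 1 (0.0137), and its median was positive without each array (0.04 to 0.06). Among 259 nuclear hormone receptors 7 rose, led by nhr-167 (1.33 ± 0.12), and 252 were not called, with 7 higher and 1 lower over the list alone (camera adjusted p = 0.336). The trehalase gene tre-2 (1.14 ± 0.11, marked) and the hexokinase gene hxk-1 (0.91 ± 0.10) rose in the sugar metabolism lists. Without 1 array the glutathione S-transferases and SKN-1 targets that rose numbered 0 (wild type 2) or 3 (wild type 3, ogt-1 mutant 1 or 2). All 4 of the genes given lost the call without wild type 2, gst-4 also without ogt-1 mutant 1, and gst-22 also without wild type 3 or ogt-1 mutant 1 or 3 (adjusted p = 0.0504 to 0.0750). The insulin-like signalling components that rose numbered 2 (wild type 2), and the nuclear hormone receptors 2 (wild type 2), 4 (wild type 3 or ogt-1 mutant 1) or 3 (ogt-1 mutant 3). Of 77 called list members followed (at most 4 per list), 17 were called in every fit without 1 array, among them ins-3, tre-2, hxk-1 and nhr-167, and 60 lost the call in at least 1 (highest adjusted p = 0.193).

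The effect of losing the O-GlcNAcase was examined by comparing the oga-1 mutant with wild type. The chemoreceptor gene srw-85 rose from 4.96 to 9.76 (log2 change 4.80 ± 0.12 SE, n = 3, limma adjusted p = 5.16e-08). The protease gene cpr-4 rose from 8.27 to 13.06 (27.6-fold, 4.79 ± 0.18, adjusted p = 1.38e-06). Other members of chemoreceptor families rose by less, including str-19 (1.64 ± 0.19), srx-68 (1.57 ± 0.20), srw-121 (1.42 ± 0.13) and srx-56 (1.33 ± 0.16). Further rises were those of nssp-55 (2.05 ± 0.16), mbug-1 (1.76 ± 0.31), ZK105.1 (1.55 ± 0.17) and the nuclear hormone receptor gene nhr-158 (1.2 ± 0.13). The wild-type means of srw-85 (4.96), str-19 (6.09), ZK105.1 (6.20), srx-68, srw-121 and mbug-1 lay below the median of 7.45. Among the genes taken by the naming rule the largest fall was that of K08B12.3 (-1.72 ± 0.15, adjusted p = 0.00187), before that of T07E3.4.

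In the oga-1 mutant 87 probe sets were called higher and 25 lower, with a median size of change of 0.80. They covered 92 genes, and 17 had no single gene name. The limit of 2-fold was passed by 29 (26 higher, 3 lower). After K08B12.3 the falls were those of T07E3.4 (-0.85 ± 0.13), nhr-43 (-0.80 ± 0.14), F40E3.5 (-0.79 ± 0.14, marked), oga-1 itself (-0.75 ± 0.10), H35N09.1 (-0.72 ± 0.10), nhr-18 (-0.65 ± 0.10), nhr-162 (-0.65 ± 0.09), the mitochondrial import gene tin-10 (-0.63 ± 0.09, marked) and the chemoreceptor gene str-268 (-0.63 ± 0.10). Of these 10 falls, that of K08B12.3 was called without each array in turn. The calls of nhr-43, F40E3.5 and str-268 were lost without any 1 of wild type 1 or 2 or oga-1 mutant 1, 2 or 3, and also without wild type 3 (nhr-43, str-268), ogt-1 mutant 1 (F40E3.5, str-268), ogt-1 mutant 2 (nhr-43, F40E3.5) or ogt-1 mutant 3 (F40E3.5), with adjusted p = 0.0572 to 0.211. Those of T07E3.4 (wild type 1 or 2, oga-1 mutant 1 or 3), H35N09.1 (wild type 2 or 3, oga-1 mutant 1 or 2), nhr-18 (wild type 1 or 2, oga-1 mutant 1, 2 or 3), nhr-162 (wild type 2 or 3, oga-1 mutant 1 or 3) tin-10 (wild type 1 or 2, oga-1 mutant 2 or 3) and oga-1 (wild type 2 or 3, oga-1 mutant 1 or 2) were lost with adjusted p = 0.0516 to 0.136. Of the 10 rises, 8 were called in every such fit. That of mbug-1 was lost without wild type 2 or 3, ogt-1 mutant 1 or oga-1 mutant 1, 2 or 3 (adjusted p = 0.0816 to 0.208). That of srx-68 was lost without wild type 2 or oga-1 mutant 1 or 2 (0.0541 to 0.0579). The count was 72, 27 and 70 without wild type 1, 2 and 3, and 48, 53 and 37 without oga-1 mutant 1, 2 and 3. It was 25 with the covariate and 9 without the 3 arrays. With the block the calls of nhr-43 (adjusted p = 0.0627) and F40E3.5 (0.0644) were lost.

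Cuticle collagens, the structural proteins of the worm's outer layer, were called higher as a list in the oga-1 mutant at camera's preset correlation. The median was 0.29 (camera adjusted p = 3.53e-31, adjusted p = 0.598 with an estimated correlation), and 0.26 after quantile normalisation. Of 147 measured, 7 rose, 0 fell and 140 were not called, and 64 were higher and 0 lower over the list alone. The estimate was positive for 144 of the 147. Examples were col-145 (0.87 ± 0.13, marked), col-180 (0.68 ± 0.10), col-119 (0.70 ± 0.11, marked) and col-157 (0.69 ± 0.11, marked). Single arrays lay 0.234, 0.180 and 0.443 above the wild-type mean for oga-1 mutant 1, 2 and 3, the last of which stood apart on the second principal component. The list stayed called without each array in turn, with medians from 0.21 (without oga-1 mutant 3) to 0.34, while its called members numbered 1 without wild type 1, oga-1 mutant 1 or oga-1 mutant 2, 0 without wild type 2 or oga-1 mutant 3 and 4 without ogt-1 mutant 3. The calls of col-145, col-180, col-119 and col-157 were lost without wild type 2 or any oga-1 mutant array, and except for col-145 also without wild type 1 (adjusted p = 0.0522 to 0.135). In the ogt-1 mutant the collagen median was 0.02 and no collagen was called over all genes or over the list alone.

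Camera called 18 of the 47 lists in the oga-1 mutant, 10 higher and 8 lower, 0 of them with an estimated correlation (lowest adjusted p = 0.598) or by fry's directional test (lowest adjusted p = 0.0757), and 8 after quantile normalisation. Fry's mixed test called 14. The count was 11 without oga-1 mutant 2 or 3. Of 1266 genes of chemoreceptor families 23 rose, 1 fell and 1242 were not called, with 35 higher and 5 lower over the list alone. Besides srw-85, those with the smallest p were srd-27 (0.84 ± 0.07), srw-121 and srx-66 (1.44 ± 0.15). The median was 0.07 (camera adjusted p = 3.66e-04, adjusted p = 0.843 with an estimated correlation), and the call was lost after quantile normalisation (adjusted p = 0.123, median 0.02), without oga-1 mutant 2 (0.0703) and without the 3 arrays (0.0828, median 0.03). This median was 0.13 without oga-1 mutant 1 and 0.04 without oga-1 mutant 3. The chemoreceptor families' 23 rises numbered 8 and 13 without wild type 2 and 3, and 11, 10 and 11 without oga-1 mutant 1, 2 and 3. Of 34 markers of body wall muscle csq-1, which encodes the calcium-binding protein calsequestrin, rose (0.71 ± 0.12) and 33 were not called, with 9 higher over the list alone. The call of csq-1 was lost without any wild-type or oga-1 mutant array or ogt-1 mutant 1 (adjusted p = 0.0684 to 0.185), and 3 genes of the body wall muscle list were called without ogt-1 mutant 3. The median was 0.09 (camera adjusted p = 4.82e-04, adjusted p = 0.757 with an estimated correlation), and 0.16 without wild type 1 and 0.14 without the 3 arrays. Among 137 moulting and hedgehog-related genes grl-20 (0.68 ± 0.11, marked) and grd-5 (0.52 ± 0.09) rose and 135 were not called, with 6 higher and 1 lower over the list alone. The call of grl-20 was lost without any 1 of the 9 arrays (adjusted p = 0.0564 to 0.178). That of grd-5 was lost without any wild-type or oga-1 mutant array or ogt-1 mutant 3 (0.0691 to 0.191), and with the block (0.0516). Their median was 0.08 (camera adjusted p = 0.00127, adjusted p = 0.757 with an estimated correlation, and adjusted p = 0.0828 without the 3 arrays, where it was 0.04), and 0.14 without oga-1 mutant 1 and 0.05 without oga-1 mutant 3.

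Of the 97 innate immune effectors mbug-1 and fip-5 (0.78 ± 0.12, marked) rose in the oga-1 mutant and 95 were not called, with 13 higher and 5 lower over the list alone. Their median was 0.10 (camera adjusted p = 0.00905, adjusted p = 0.757 with an estimated correlation, and adjusted p = 0.0782 without oga-1 mutant 2). The call of fip-5 was lost without wild type 1 or 2 or oga-1 mutant 2 or 3 (adjusted p = 0.0703 to 0.135). Among 259 nuclear hormone receptors nhr-158, nhr-167 (0.99 ± 0.12) and nhr-159 (1.02 ± 0.12) rose, nhr-162, nhr-18 and nhr-43 fell and 253 were not called, with 6 higher and 4 lower over the list alone. Their median was -0.03 (camera adjusted p = 0.0211, adjusted p = 0.598 with an estimated correlation), and the call was lost without wild type 2 (adjusted p = 0.0547), oga-1 mutant 1 (0.0626) or oga-1 mutant 3 (0.0657). Their median was -0.02 without wild type 3, and -0.05 after quantile normalisation or without the 3 arrays. The call of nhr-159 was lost without wild type 2 (0.0645), and the 3 falls numbered 1 without wild type 1 or 3 or oga-1 mutant 2 and 0 without wild type 2 or oga-1 mutant 1 or 3. Of 8 genes of the hexosamine and O-GlcNAc pathway the deleted oga-1 fell and 7 were not called, with 1 lower over the list alone. The median was -0.11 (camera adjusted p = 0.0212, adjusted p = 0.598 with an estimated correlation, and adjusted p = 0.0995 without oga-1 mutant 3). It was -0.21 without wild type 1 and -0.07 without wild type 2. The call was also lost after quantile normalisation (adjusted p = 0.0612), without the 3 arrays (0.0828) and on ranks (0.0504). With the covariate the calls of innate immune effectors (adjusted p = 0.0534, median 0.06), nuclear hormone receptors (0.0534, median -0.02) and the hexosamine and O-GlcNAc pathway (0.0847, median -0.06) were lost. Without oga-1 the hexosamine list was not tested, so a lower pathway is not shown. Of 73 genes of autophagy and lysosome cpr-4 rose, against a list median of -0.06, and 72 were not called, with 1 higher over the list alone. That list was called lower (camera adjusted p = 0.0212, adjusted p = 0.757 with an estimated correlation), and the call was lost after quantile normalisation (adjusted p = 0.0961), without wild type 2 (0.0581), without oga-1 mutant 3 (0.238) and without the 3 arrays (0.103). The list median was -0.04 without wild type 2 or 3 and -0.03 without oga-1 mutant 3.

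No member was called over all genes or over the list alone in several lists that camera called in the oga-1 mutant. The germline and maternal genes (48 measured) had a median of -0.10 (camera adjusted p = 0.00191, adjusted p = 0.757 with an estimated correlation), with fbf-2 at -0.43 ± 0.11 (adjusted p = 0.183, marked) and cgh-1 at -0.32 ± 0.09 (adjusted p = 0.241). The germline median was -0.05 without wild type 2 and -0.07 without oga-1 mutant 2. The germline call was lost with the covariate (adjusted p = 0.104, median -0.04). The mid and late embryo patterning genes (61 measured) had a median of 0.10 (camera adjusted p = 0.00905, adjusted p = 0.757 with an estimated correlation), with end-3 at 0.38 ± 0.14 (adjusted p = 0.347) and sdz-36 at 0.22 ± 0.08 (adjusted p = 0.352). The sperm genes (77) had a median of 0.12 (camera adjusted p = 0.0150, adjusted p = 0.757 with an estimated correlation), and their call was lost without wild type 3 (adjusted p = 0.0671) or oga-1 mutant 2 (0.0708). The genes of fatty acid synthesis and desaturation (38) had a median of -0.11 (camera adjusted p = 0.0169, adjusted p = 0.757 with an estimated correlation), and their call was lost without wild type 1 (adjusted p = 0.153) or oga-1 mutant 3 (0.221), with a median of -0.02 in each. After quantile normalisation the calls of mid and late embryo patterning genes (adjusted p = 0.0513), sperm genes (0.0844) and fatty acid synthesis and desaturation (0.0703) were lost, and without the 3 arrays those of mid and late embryo patterning genes (0.0586, median 0.06) and fatty acid synthesis and desaturation (0.718, median -0.01). The remaining 6 lists were small RNA pathways (median -0.06, camera adjusted p = 0.0150), nucleolus and RNA polymerase I (-0.08, 0.0327), DAF-16 repressed targets (0.12, 0.0331, with 3 of 17 genes higher over the list alone), C-type lectins (0.06, 0.0453), UDP-glucuronosyltransferases (-0.06, 0.0476) and yolk proteins (0.15, 0.0489). For these, adjusted p = 0.757 with an estimated correlation, except for the nucleolus list (adjusted p = 0.861). Without wild type 1 and 2 and oga-1 mutant 1 and 2 the median of small RNA pathways was -0.10, -0.04, -0.11 and -0.04. Without oga-1 mutant 1, 2 and 3 that of the nucleolus list was -0.19, -0.05 and -0.01. Without wild type 1 and 3 and oga-1 mutant 1 and 3 that of UDP-glucuronosyltransferases was -0.01, -0.04, -0.10 and -0.04, and that of yolk proteins was 0.10 without oga-1 mutant 3. All 6 lost the call without 1 array. Small RNA pathways lost it without wild type 2 or oga-1 mutant 2 or 3 (adjusted p = 0.0697 to 0.159), the nucleolus list without wild type 1 or oga-1 mutant 2 or 3 (0.135 to 0.687) and DAF-16 repressed targets without wild type 3 or oga-1 mutant 1 or 2 (0.10 to 0.214). C-type lectins lost it without wild type 2 or 3 or oga-1 mutant 2 or 3 (0.0779 to 0.255), UDP-glucuronosyltransferases without wild type 1, ogt-1 mutant 1 or 3 or oga-1 mutant 3 (0.0507 to 0.417), and yolk proteins without wild type 1 or 2, ogt-1 mutant 1 or 3 or any oga-1 mutant array (0.0509 to 0.153). Quantile normalisation ended the calls of small RNA pathways (0.0944), nucleolus (0.250), C-type lectins (0.505, median 0.02) and yolk proteins (0.0944). The block ended those of DAF-16 repressed targets (0.0891), C-type lectins (0.0891) and yolk proteins (0.0505). Camera on ranks ended those of DAF-16 repressed targets (0.0504) and UDP-glucuronosyltransferases (0.0504), and the mean of a gene's probe sets that of yolk proteins (0.207). The covariate ended those of small RNA pathways (0.0598, median -0.04), nucleolus (0.173), DAF-16 repressed targets (0.12) and C-type lectins (0.338), and leaving out the 3 arrays those of UDP-glucuronosyltransferases (0.718, median -0.01), yolk proteins (0.344, median 0.09) and nucleolus (0.886), where the nucleolus median turned to 0.07. That of small RNA pathways was then -0.10. Of 16 called list members followed, srd-27, srx-66 and nhr-167 were called in every fit without 1 array and 13 lost the call in at least 1 (highest adjusted p = 0.191).

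**Figure D3:**
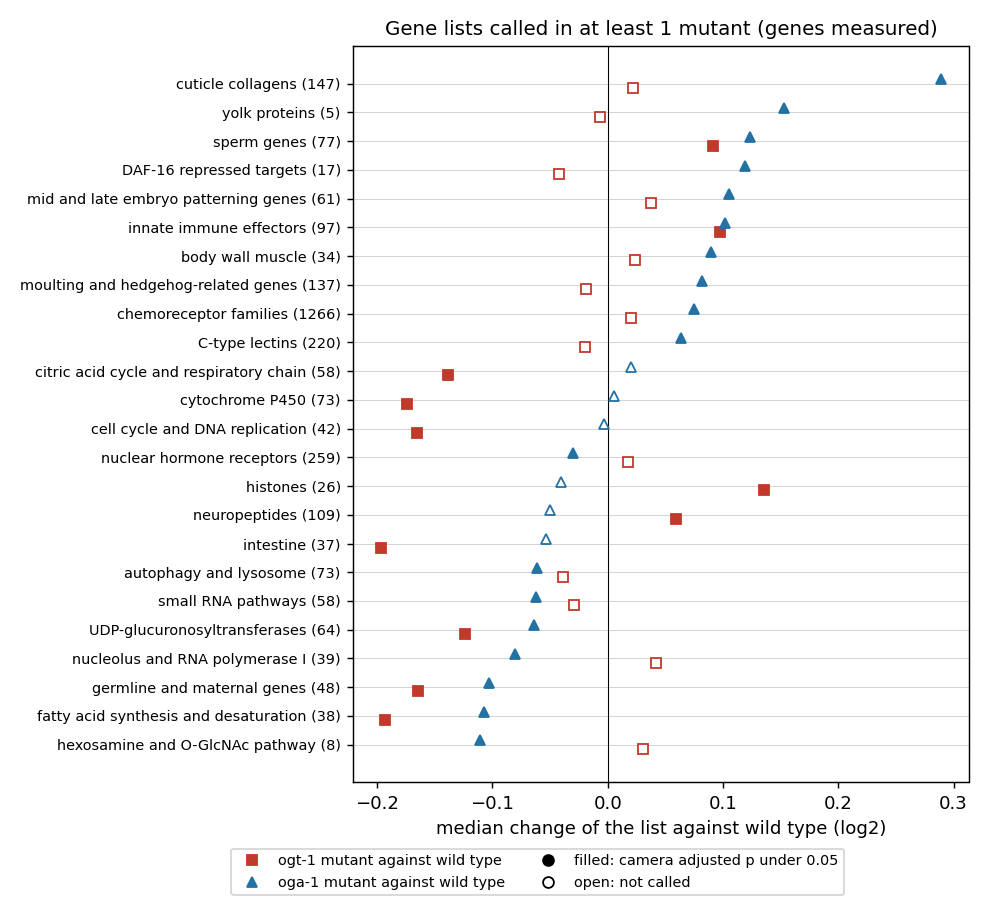
Median log2 change against wild type of the lists called by camera in at least 1 mutant, with squares for the ogt-1 mutant and triangles for the oga-1 mutant, filled where camera's adjusted p was under 0.05 and open where it was not. The number of genes measured stands in parentheses. Cuticle collagens lie at 0.29 in the oga-1 mutant and 0.02 in the ogt-1 mutant, and no filled list was called with an estimated correlation.

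Comparing the mutants directly tested where they differed. The signal of srw-85 was lower in the ogt-1 mutant than in the oga-1 mutant (log2 difference -4.90 ± 0.12 SE, n = 3, limma adjusted p = 4.16e-08). The difference was -3.86 ± 0.32 for pud-4, -3.48 ± 0.41 for pud-3, -3.11 ± 0.30 for T22F3.11 (marked), -2.82 ± 0.58 for T02B11.4 and -2.49 ± 0.18 for lips-15. Higher in the ogt-1 mutant were shc-1 (2.92 ± 0.19, marked), clec-3 (1.85 ± 0.21), ugt-13 (1.75 ± 0.19), K08E7.5 (1.73 ± 0.14, marked), the solute carrier gene slc-17.5 (1.70 ± 0.11) and F56A4.10 (1.67 ± 0.19, marked). The lower mean lay below the median of 7.45 for srw-85 (4.86), pud-4, pud-3, T22F3.11, T02B11.4, clec-3, ugt-13, K08E7.5 and F56A4.10. In total 652 probe sets were called, 297 higher and 355 lower in the ogt-1 mutant, of which 100 passed the limit of 2-fold (36 higher, 64 lower). They covered 555 genes, and 57 had no single gene name. Of the 12 genes named, T02B11.4 lost the call without wild type 2, ogt-1 mutant 1 or 2 or oga-1 mutant 1, 2 or 3 (adjusted p = 0.0612 to 0.111). The count was 360 and 383 without wild type 2 and 3, 267 and 255 without ogt-1 mutant 1 and 3, and 326 and 296 without oga-1 mutant 2 and 3. With the block it was 1128 (518 higher, 610 lower), with the control gap, which parted the mutants completely, as a covariate 9, without the 3 arrays 188, and without probe sets marked for cross-hybridisation 371.

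Between the mutants the list of cuticle collagens was called lower in the ogt-1 mutant at camera's preset correlation. The median difference was -0.29 (camera adjusted p = 1.70e-18, adjusted p = 0.834 with an estimated correlation). Of 147, 0 were higher, 26 were lower and 121 were not called, and 58 were lower over the list alone. Examples were col-159 (-1.47 ± 0.21, marked), col-145 (-0.84 ± 0.13, marked), col-95 (-0.70 ± 0.11, marked) and col-77 (-0.67 ± 0.09). The median was -0.16 with the covariate and -0.17 without the 3 arrays. The called collagens numbered 15 and 16 without wild type 2 and 3, 9 and 9 without ogt-1 mutant 1 and 3, and 11 and 10 without oga-1 mutant 2 and 3. The citric acid cycle and respiratory chain list was called lower too, with a median of -0.14 (camera adjusted p = 5.79e-05, adjusted p = 0.834 with an estimated correlation, and adjusted p = 0.675 with the covariate, where it was -0.03). The isocitrate dehydrogenase genes idhg-2 (-0.71 ± 0.13) and idhb-1 (-0.40 ± 0.09) and sdha-2 (-0.67 ± 0.12, marked) were lower, 55 of 58 were not called, and 5 were lower over the list alone. Its 3 lower genes numbered 0 without ogt-1 mutant 1 or oga-1 mutant 2 or 3, 1 without ogt-1 mutant 3 or oga-1 mutant 1 and 5 without ogt-1 mutant 2. The call of idhg-2 was lost without ogt-1 mutant 1 or 3 or oga-1 mutant 2 or 3 (adjusted p = 0.0660 to 0.0732) and that of sdha-2 without ogt-1 mutant 1 or any oga-1 mutant array (0.0524 to 0.0678). That of idhb-1 was lost without any 1 array but ogt-1 mutant 2 (0.0513 to 0.141). Of 259 nuclear hormone receptors 11 were higher in the ogt-1 mutant, 0 were lower and 248 were not called, with 14 higher over the list alone. They included nhr-43 (1.09 ± 0.14), nhr-162 (0.96 ± 0.09), nhr-18 (0.70 ± 0.10) and nhr-180 (0.67 ± 0.11). The median was 0.02 (camera adjusted p = 0.00421, adjusted p = 0.810 with an estimated correlation), and 0.04 without oga-1 mutant 3 and 0.05 after quantile normalisation. Of 220 C-type lectins clec-3, clec-73 (0.66 ± 0.11, marked) and clec-143 (0.47 ± 0.07) were higher, 4, including clec-1 (-1.11 ± 0.20), were lower and 213 were not called, with 4 higher and 12 lower over the list alone. The median was -0.11 (camera adjusted p = 0.00273, adjusted p = 0.834 with an estimated correlation, and adjusted p = 0.512 with the covariate), and -0.06 both with that covariate and after quantile normalisation. The 4 lower lectins were 7 and 8 without wild type 1 and ogt-1 mutant 2, 1 without wild type 2 or 3, ogt-1 mutant 3 or oga-1 mutant 3, and 0 without ogt-1 mutant 1 or oga-1 mutant 2. The call of clec-73 was lost without ogt-1 mutant 1 or oga-1 mutant 2 (adjusted p = 0.0544 to 0.0570) and that of clec-1 without ogt-1 mutant 1 or 3 or oga-1 mutant 2 or 3 (0.0591 to 0.0799). That of nhr-180 was lost without ogt-1 mutant 1 (0.0506). The 11 nuclear hormone receptors were 7 without wild type 2 or 3, ogt-1 mutant 2 or oga-1 mutant 1, 5 without ogt-1 mutant 1, 4 without ogt-1 mutant 3 and 6 without oga-1 mutant 3.

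Camera called 14 lists between the mutants, 7 higher and 7 lower in the ogt-1 mutant, 0 of them with an estimated correlation (lowest adjusted p = 0.810) or by fry's directional test (lowest adjusted p = 0.0865). Fry's mixed test called 38. Neuropeptides (1 of 109 higher, ins-11 at 0.76 ± 0.16, marked, and 0 over the list alone) had a median of 0.11 (camera adjusted p = 5.79e-05, adjusted p = 0.834 with an estimated correlation), and 0.06 and 0.18 without oga-1 mutant 1 and 3 and 0.19 without the 3 arrays. Neurons (2 of 37 higher, rgef-1 at 0.58 ± 0.12 and che-3 at 0.45 ± 0.10, marked, with 2 over the list alone) had a median of 0.14 (camera adjusted p = 0.00684, adjusted p = 0.834 with an estimated correlation), and 0.08 without oga-1 mutant 1. The call of ins-11 was lost without wild type 2, ogt-1 mutant 1 or 2 or any oga-1 mutant array (adjusted p = 0.0640 to 0.104) and that of rgef-1 without wild type 2 or 3, any ogt-1 mutant array or oga-1 mutant 2 or 3 (0.0542 to 0.109). That of che-3 was lost without any 1 array but wild type 1 (0.0567 to 0.132). None of 26 histones was called over all genes or over the list alone, and their median was 0.18 (camera adjusted p = 0.00122, adjusted p = 0.834 with an estimated correlation), and 0.30 without the 3 arrays. Of 137 moulting and hedgehog-related genes ptr-6 (0.84 ± 0.13, marked) and ptr-17 (0.76 ± 0.13) were higher, 6, including nas-28 (-0.97 ± 0.16) and grl-20 (-0.65 ± 0.11, marked), were lower and 129 were not called, with 2 higher and 9 lower over the list alone. Their median was -0.13 (camera adjusted p = 0.0130, adjusted p = 0.834 with an estimated correlation, and adjusted p = 0.122 without oga-1 mutant 3, where it was -0.08, as after quantile normalisation), and the 6 lower genes of moulting and hedgehog-related genes were 3 without wild type 2, 1 without ogt-1 mutant 1, 2 without ogt-1 mutant 3 or oga-1 mutant 2, and 0 without oga-1 mutant 3. The calls of ptr-17 (without ogt-1 mutant 1 or 3), nas-28 (ogt-1 mutant 3 or oga-1 mutant 3) and grl-20 (ogt-1 mutant 1 or oga-1 mutant 3) were lost with adjusted p = 0.0501 to 0.0684, and without the 3 arrays the list was lost (0.146, median -0.07). Of 42 genes of cell cycle and DNA replication 3 were lower, led by rnr-1 (-0.86 ± 0.12, marked), and 39 were not called, with 2 higher and 5 lower over the list alone. Their median was -0.15 (camera adjusted p = 0.0414, adjusted p = 0.834 with an estimated correlation), and the call was lost with the block (adjusted p = 0.0665) and without ogt-1 mutant 1 (0.0568), ogt-1 mutant 2 (0.136) or oga-1 mutant 1 (0.553, median -0.08), with 1 lower gene instead of 3 without ogt-1 mutant 3. Chromatin regulators (median 0.09, camera adjusted p = 0.0151), nucleolus and RNA polymerase I (0.10, 0.0374), intestine (-0.17, 0.0374), cytochrome P450 (-0.15, 0.0383) and insulin-like signalling components (0.03, 0.0441) were called as well, each with adjusted p = 0.834 with an estimated correlation. The chromatin median was 0.03 and 0.04 without ogt-1 mutant 3 and oga-1 mutant 2, and the intestine median -0.10 without oga-1 mutant 1. The nucleolus median was 0.04 without ogt-1 mutant 1, and 0.24, 0.04 and 0.03 without oga-1 mutant 1, 2 and 3. The insulin median turned to -0.03 without ogt-1 mutant 3 and -0.01 without oga-1 mutant 2, and was 0.07 without oga-1 mutant 3, 0.01 with the covariate and 0.09 without the 3 arrays. These 5 calls were lost in fits without 1 array. The chromatin list (chromatin and H3K4, Polycomb regulators) was lost without ogt-1 mutant 3 (adjusted p = 0.106) or oga-1 mutant 2 (0.153), the nucleolus list without ogt-1 mutant 1 (0.195) or 3 (0.0532) or oga-1 mutant 2 (0.255) or 3 (0.523), and the intestine list without ogt-1 mutant 1 (0.163) or 3 (0.0910) or oga-1 mutant 1 (0.396) or 2 (0.0678). The cytochrome P450 list was lost without ogt-1 mutant 1 (0.0690) or 3 (0.129) or oga-1 mutant 2 (0.153), and the insulin list without ogt-1 mutant 2 (0.0567) or 3 (0.168) or oga-1 mutant 2 (0.153). With the covariate the calls of chromatin (0.313, median 0.04), nucleolus (0.774, median 0.02), intestine (0.990, median -0.06), cytochrome P450 (0.616, median -0.06) and insulin (0.0516) were lost, after quantile normalisation those of chromatin (0.0818), nucleolus (0.168), cytochrome P450 (0.0556) and insulin (0.0750), and without the 3 arrays that of nucleolus (0.857), whose median turned to -0.04. Camera on ranks did not call the insulin list (adjusted p = 0.110). Of 81 called list members followed, 29 were called in every fit without 1 array and 52 lost the call in at least 1 (highest adjusted p = 0.152).

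Genes called in both mutants were compared in direction. Both mutants raised cpr-4 (4.55 and 4.79), nssp-55 (1.4 ± 0.16 and 2.05 ± 0.16), srx-68 (1.55 ± 0.20 and 1.57 ± 0.20), srx-56 (1.58 ± 0.16 and 1.33 ± 0.16) and str-19 (1.32 ± 0.19 and 1.64 ± 0.19) and lowered K08B12.3 (-1.62 and -1.72). The difference between the mutants was not called for any of these 6 genes, and it was -0.23 ± 0.18 for cpr-4 and -0.65 ± 0.16 for nssp-55 (adjusted p = 0.486 and 0.0579). Opposite changes were found for C25G4.7 (-1.16 ± 0.09 in the ogt-1 mutant and 0.62 ± 0.09 in the oga-1 mutant), srg-2 (-0.66 ± 0.10 and 0.68 ± 0.10), osm-11, a secreted ligand of Notch receptors (-0.71 ± 0.12 and 0.80 ± 0.12, marked), and tag-344 (-0.39 ± 0.08 and 0.68 ± 0.08). The wild-type means of C25G4.7, srg-2 and tag-344 lay below the median of 7.45. Without each array in turn C25G4.7 and srg-2 were called in the ogt-1 mutant and tag-344 in the oga-1 mutant. The call of osm-11 was lost in the ogt-1 mutant without wild type 2 or 3 or ogt-1 mutant 1 or 3 (adjusted p = 0.0656 to 0.0908) and in the oga-1 mutant without any wild-type array or oga-1 mutant 2 or 3 (0.0554 to 0.134). That of tag-344 in the ogt-1 mutant was lost without any 1 array but oga-1 mutant 1 (0.0518 to 0.170). In the oga-1 mutant srg-2 was lost without wild type 1 or 2 or any oga-1 mutant array (0.0554 to 0.112) and C25G4.7 without any wild-type or oga-1 mutant array (0.0501 to 0.107).

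**Figure D4:**
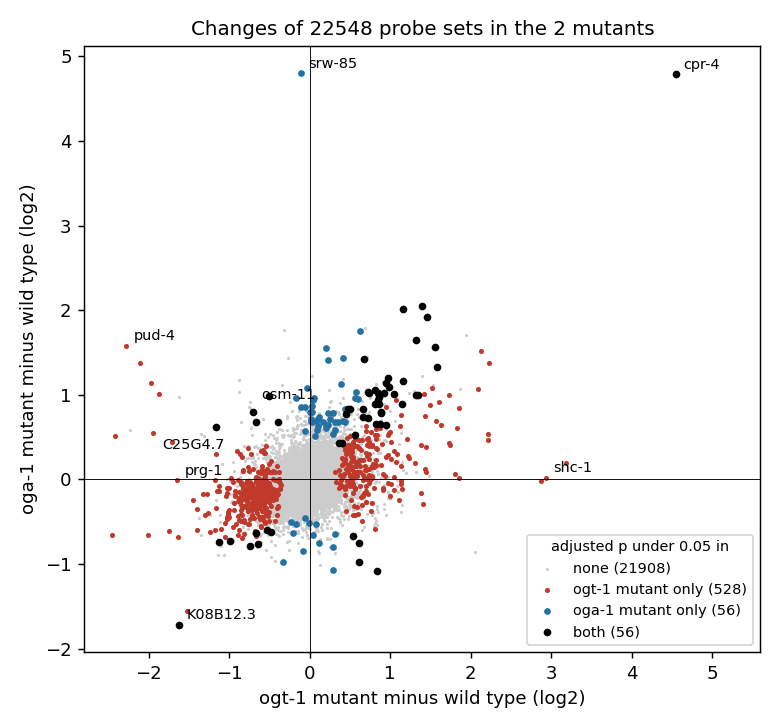
Log2 change of each of 22548 probe sets in the ogt-1 mutant (x axis) and in the oga-1 mutant (y axis) against the same 3 wild-type arrays, coloured by the comparison in which limma's adjusted p was under 0.05. The 56 probe sets called in both are black, with cpr-4 at 4.55 and 4.79 and K08B12.3 at -1.62 and -1.72.

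In both mutants 56 probe sets were called, 39 higher in both, 8 lower in both and 9 in opposite directions. Independent lists of these lengths would share 2.9, with 1.03 higher in both and 0.350 lower in both. Unchanged mutants set against 1 simulated wild-type group shared 0.01 on average (at most 1), but such groups give almost no calls. Simulated mutants with unrelated changes at the called probe sets alone had 517 and 102 calls on average and shared 2.47 in the same direction (0 to 8). With smaller changes assumed at all others too they had 1267 and 298 calls and shared 30.7 (16 to 52). The part that the shared wild-type arrays add to the 47 thus depends on the sizes assumed. Of probe sets called in both mutants with 2 of the wild-type arrays, set against the array left out, 30 of 42 (wild type 1), 15 of 15 (wild type 2) and 24 of 35 (wild type 3) kept at least 0.5 of their change in both mutants. Of the 47 in the same direction 3 were called as different between the mutants, including srw-121 (-0.75, adjusted p = 0.0200) and srd-27 (-0.36, adjusted p = 0.0343). The count of 47 was 15 without wild type 2, 29 without ogt-1 mutant 1, and 24, 28 and 25 without oga-1 mutant 1, 2 and 3, and it was 8 with the covariate and 5 without the 3 arrays. Across probe sets, which are not independent replicates, the log2 changes of the mutants correlated with r = 0.330, against 0.499 on average in simulations without effects. The observed covariance was 0.0169 and the simulated one 0.00890, a difference of 0.00803. With the wild-type arrays divided between the comparisons r was 0.108 and the covariance 0.00654. Of the 34 named genes higher in both mutants 14 belonged to chemoreceptor families, against 7.4% of all genes (41.2%, odds ratio 8.85, 95% interval 4.12 to 18.5, Fisher's exact adjusted p = 2.19e-06 over 47 lists).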

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

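The tests of a difference of stocks, of developmental time, of ogt-1 mutant 1 alone, of linked sequence and of shared noise (a wild-type array left out of the choice, and unrelated changes) were chosen after the results had been seen, as was the covariate for the control gap.

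The probe sets that follow were chosen as called in opposite directions in the 2 mutants, so the difference between the mutants follows from that choice and adds only its size. The difference of ogt-1 mutant minus oga-1 mutant was -1.50306 and -1.49712 log2 at the 2 probe sets of osm-11, -1.77875 for C25G4.7, -1.34854 for srg-2 and -1.06489 for tag-344. The other 4, which have no single gene name, gave 1.59818, 1.20052, 1.35835 and 1.91627.

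In both mutants 47 probe sets, cpr-4 among them, were called in the same direction, 3 of them with a called difference between the mutants. One wild-type array stays open, except for calls left without it (15 without wild type 2). It helped choose the rest, so sizes kept (96.3% or more) cannot tell. Signal shared between related genes is argued against by the odds ratio of marked probe sets, 0.345 (95% interval 0.12 to 0.817). Noise of the shared wild-type arrays stays open as a cause of part of the 47. Simulated mutants with unrelated changes at the called probe sets alone had 517 and 102 calls, near the real numbers, and shared 2.47 on average (0 to 8). With smaller changes assumed beyond those they shared 30.7 (16 to 52), but made more calls than the data (1267 and 298). Probe sets called with 2 wild-type arrays kept a median of at least 68.3% of their change against the array left out, short of the limit of 80% set for it, but 30 of 42, 15 of 15 and 24 of 35 kept at least 0.5 of it in both mutants, which noise as the cause of all would not leave. A wild-type stock that differed from both mutant stocks beyond the deletions would give the same 47 and stays open, as all 3 wild-type arrays may share 1 stock.

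Cuticle collagens were higher in the oga-1 mutant with a list median of 0.29 by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.598) or by fry's directional test (adjusted p = 0.0757). One array is argued against by the lowest median without 1 array, 0.209, only just above the limit of 0.2 set for it. A further condition was added after that median was seen, to exceed 0.5 of the full value (0.144) by more than the SD of these medians (0.0446). Signal shared between related genes is argued against by the median of 0.263 for the 86 collagens with unmarked probe sets, and a shift of all probe sets of like brightness by a highest median of 0.0963 among 10000 random lists. A difference in developmental time at collection stays open: oga-1 mutant 1, 2 and 3 lay 0.234, 0.180 and 0.443 above the wild-type mean, the most in the array that stood apart, collagen genes are transcribed in waves in each moulting cycle, and no sample gives the time course.

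Genes changed in the ogt-1 mutant were weighed against the quality of its RNA and arrays. ogt-1 mutant array 1 alone stays open, except for the 178 of 584 calls left without it. It helped choose the rest, so the size kept (96.6%) cannot tell. Loss of 5-prime signal in the ogt-1 mutant RNA stays open. With the covariate, which omits catalase, 100% of called probe sets kept at least 0.5 of their change. It is fitted within groups, where called probe sets tend to vary little, so this cannot decide. The median SE grew from 0.118 to 0.161 and 49 of 584 calls remained. The 5-prime catalase probe set itself gave -0.894. Sequence linked to the deletion stays open, as only effects on neighbours were tested. Called genes showed no excess near ogt-1 (odds ratio 0.620, 0.246 to 1.30). Near oga-1 the odds ratio in the oga-1 mutant was 2.00 (0.529 to 5.34).

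For the count of genes differing, dividing the 6 arrays of a comparison in every other way gave at most 0 called probe sets against 584 (ogt-1 mutant against wild type) and 652 (between the mutants) for the real groups, and 87 higher and 25 lower for oga-1 mutant against wild type. The real division was thus 1 of 10 in each comparison, which is too few divisions for a share under 0.05.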

How the results depend on the processing

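The covariate for the control gap and the fit without 3 arrays that stood apart were tests chosen after the results had been seen, and the other choices were made before the data were examined. The counts of probe sets called (584 in the ogt-1 mutant, 87 higher and 25 lower in the oga-1 mutant and 652 between the mutants) stayed within 1.5 times under quantile normalisation, median centring, removal of dim probe sets, the trended and robust prior and 1 probe set per gene. They were 65, 4 and 90 without moderation, 270, 46 and 336 with only the 2 groups compared, 105, 29 and 100 at the 2-fold limit, and 118, 29 and 113 at an adjusted p under 0.01. Array weights gave 1295 in the ogt-1 mutant, the replicate block 1034 there and 1128 between the mutants, and removal of probe sets marked for cross-hybridisation 371 between the mutants. The control gap as a covariate left 49, 25 and 9, and leaving out the 3 arrays that stood apart 262, 9 and 188. Without 1 array the counts ran from 138 to 533, 27 to 96 and 255 to 803. The stricter limits lower the counts by construction, and otherwise the cause was not tested.

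The 47 probe sets called in both mutants in the same direction were 3 without moderation, 20 with only the 2 groups compared, 71 with the replicate block, 10 at the 2-fold limit, 16 at an adjusted p under 0.01, 8 with the covariate, 5 without the 3 arrays, and 15 to 42 without 1 array. The correlation of the mutants' changes (0.330) ran from 0.276 to 0.431 without 1 array and was 0.108 with the wild-type arrays divided. The gene lists called numbered 0, 0 and 0 with an estimated correlation and 0, 0 and 0 by fry's directional test, while its mixed test called 33, 14 and 38. In the oga-1 mutant they numbered 8 after quantile normalisation, 11 with the covariate and 10 without the 3 arrays. Without 1 array they ran from 8 to 17, 11 to 21 and 10 to 16 in the 3 comparisons. Of the 43 list calls 2 turned in camera's direction, nucleolus and RNA polymerase I in the oga-1 mutant without the 3 arrays (adjusted p = 0.886) and intestine between the mutants with the covariate (adjusted p = 0.990), neither called. The nucleolus median also turned between the mutants without the 3 arrays, to -0.04.

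The call of the dimmer ogt-1 probe set in the ogt-1 mutant was lost without moderation (0.70) and with the covariate (0.76), and its log2 change ran from 0.65 to 0.80 without 1 array. The call of the oga-1 probe set with suffix _s_at in the oga-1 mutant was lost without moderation (-0.75), with only the 2 groups compared (-0.75), with the covariate (-0.75) and without the 3 arrays (-0.90), and its change ran from -0.84 to -0.68 without 1 array. The unmarked oga-1 probe set ran from -0.70, where it was called, to -0.52. Of 64 results for named genes, all 64 kept their direction in every alternative, 38 kept the call without each array in turn, and 45 lost it without moderation. Arrays with the same replicate number in oga-1 mutant and wild type gave r = 0.12, 0.00520 and 0.214, so the number was not taken to pair them, and the block called 163 there. There it ended the calls of 3 lists (DAF-16 repressed targets, C-type lectins, yolk proteins) and of nhr-43, F40E3.5, grd-5 and nlp-5. In the 2 comparisons that the check paired it ended, among those named, only the calls of the cell cycle list, rpl-11.1, sqv-8 and cyp-14A4. Another pseudocount was not run, as the values are logarithms.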

Other observations

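The tests of chromosomes below were chosen after the results had been seen.

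Of 14 genes of the hypoxia and H2S response, 3 rose in the ogt-1 mutant, 1 fell and 10 were not called, with 5 higher and 1 lower over the list alone. The gene rhy-1, a regulator of the hypoxia-inducible factor HIF-1, rose by 1.05 ± 0.14. The odds ratio of a rise was 21.7 (Fisher's exact adjusted p = 0.0101 over 47 lists), but fry's directional test gave no call. Camera gave adjusted p = 0.0517 (0.824 with an estimated correlation). It was under 0.05 after quantile normalisation (0.0496), with the block (0.0477) or covariate (0.00320), and without the 3 arrays (0.0199), wild type 3 (0.0182) or ogt-1 mutant 1 (0.00553). The call of rhy-1 was kept without each array, but the rises numbered 1 without wild type 2 or 3 or ogt-1 mutant 1, and the fall was lost without any wild-type array, ogt-1 mutant 1 or 3 or oga-1 mutant 1.

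Called genes were unevenly spread over the chromosomes of the WBcel235 assembly. In the ogt-1 mutant 151 of 4317 genes on chromosome V were called (3.50%, odds ratio 1.4, Fisher's exact adjusted p = 0.00624 over 6 chromosomes), and the odds ratio was 1.49 without chemoreceptor genes (adjusted p = 0.00222). In the oga-1 mutant 38 of 4317 were called on chromosome V (odds ratio 2.21, adjusted p = 9.94e-04), and the odds ratio was 1.38 without chemoreceptor genes (adjusted p = 0.436). On chromosome X, which carries oga-1, 19 of 2351 were called (odds ratio 1.71, adjusted p = 0.0665), with an odds ratio of 2.42 without chemoreceptor genes (adjusted p = 0.00863), which leaves sequence linked to the oga-1 deletion open. On chromosome I called genes were fewer in the oga-1 mutant (2 of 2469, odds ratio 0.135, adjusted p = 9.94e-04, and 0.00863 without chemoreceptor genes). In the ogt-1 mutant (odds ratio 0.693, adjusted p = 0.0420) that call was lost without them (0.0533).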
